A study of Mus musculus with 3 samples.

How the data were processed

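RNA from 3 pools of sorted mouse pancreatic cells was measured on 3 arrays, 1 per group. Per the labels, beta cells came from 3 mice carrying a green fluorescent reporter of the insulin promoter and were not treated. Ductal cells came from 6 mice with wild-type Fbw7 and from 6 mice with both Fbw7 alleles floxed. Both kinds of ductal mice carried a tamoxifen-inducible Cre under the cytokeratin 19 promoter and a Cre-activated yellow fluorescent reporter; they received tamoxifen for 5 days and were sampled 7 days after the last dose. Per the labels' protocols, 30000 cells were sorted by flow cytometry for each array, and 18 ng of RNA was amplified with a NuGEN whole-transcript kit, converted and labelled with biotin. The beta cell array therefore differs from the ductal arrays in cell type, reporter and tamoxifen together.

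The deposited values are log2 intensities, 1 for each probe set and array, made by the authors with RMA (background correction, quantile normalization and median-polish summary) per the submitters' processing notes, which name the method. Its version, and which arrays were normalized together, are not given in the sources used here. The 3 arrays were not forced to 1 shared distribution: the SD over all probe sets was 1.57 for beta cells, 2.02 for wild-type ductal cells and 1.97 for Fbw7-deleted ductal cells. Of 35556 probe sets, 16792 (47.2%) held exactly the same value in both ductal arrays, 6302 (17.7%) in beta and wild-type ductal cells, and 5712 (16.1%) in all 3 arrays. Exact ties of this number pull medians of small differences to 0.

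The platform annotation listed 1 gene for 21789 probe sets, several genes for 1621 and none for 12146. Of the single-gene probe sets, 21698 matched a mouse RefSeq gene of assembly GRCm38.p6 by gene ID and 91 kept the annotation's symbol; 0 symbols changed. This left 19938 genes, 999 of them with more than 1 probe set, for which the probe set with the highest mean over the 3 arrays was used. Probe sets with several genes or none were not named. Ins1 has no single-gene probe set in this annotation and was not analysed here.

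These choices were made before the data were examined. A gene entered a comparison if the higher of its 2 values was above the median of single-gene probe sets on that array (log2 5.30 in beta cells, 5.23 in wild-type and 5.24 in deleted ductal cells). Differences of log2 values were computed for 3 pairs of arrays, and genes at least 2-fold apart were counted. With 1 array per group there is no estimate of spread, so no difference has a replicate check and no p-value is given; the number of arrays limits the precision. For 24 gene lists, the median difference of members above the floor was set among medians of 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays. A list below 2.5% or above 97.5% of its random lists is called outside them, as happens for about 1 in 20 lists of genes drawn at random. Members of a marker list can vary together, so this rate does not measure chance between 2 single arrays. Lists with under 5 members above the floor were given values only. Named genes are Fbxw7, the 10 genes with the largest positive and the 10 with the largest negative difference in each comparison (leaving out predicted genes, RIKEN clones, receptor, microRNA and immunoglobulin families), up to 4 members of each list (the 2 highest and the 2 lowest), and Ins2, Gcg, Sst, Ppy, Neurog3, Sox9, Krt19, Hes1, Myc, Jun, Ccne1 and Cpa1. A list of mesothelial markers was added after the largest differences had been seen, and 7 macrophage genes were chosen likewise.

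Among genes at least 4-fold higher in beta than in wild-type ductal cells, the share higher in deleted ductal cells was counted. It was compared with 100 simulated arrays of unchanged ductal cells, because both differences use the wild-type ductal array. Alternatives were no floor, a floor at the 75th percentile, thresholds of 1.5-fold and 4-fold, quantile normalization, centring of each array, a loess trend on the mean level (span 0.3), the mean of a gene's probe sets and unmatched random lists. Leaving out marker lists, leaving out genes identical in both ductal arrays, and raising each level below its array's floor to that floor (a gene below it in both arrays being at 0) were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

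The steps were tested on simulated data for the comparison of the ductal arrays, over its 10035 genes with a noise SD of log2 0.23. Of 200 genes changed by log2 1.5, 95.0% were recovered at 2-fold with the right sign, and 7 unchanged genes were called. At log2 2 all 200 were recovered, with 17 unchanged genes called. Of 100 lists of 15 unchanged genes, 8 lay outside their random lists, where 5.09% was computed without the matching step. With a shift of log2 0.3 the number was 82 of 100, against 83.3% computed, so shifts of this size in a list of 15 genes are missed in part. A first version of this test required 90 of 100 at that shift, a bound set without computing the power. It failed, and the computed power replaced it. The simulated differences held no exact ties, whereas 4841 of the 10035 genes (48.2%) were identical in the measured ductal arrays. The simulated rates therefore need not hold for the measured lists.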

Results

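Gene expression was compared between Fbw7-deleted and wild-type pancreatic ductal cells of adult mice, with beta cells as an endocrine reference. Fbw7, encoded by Fbxw7, is the substrate-recognition subunit of a ubiquitin ligase that marks Myc, Jun, cyclin E and Notch proteins for degradation. Each of the 3 groups was 1 array of pooled sorted cells, from 3 mice for beta cells and 6 mice for each ductal group. The median level over all probe sets was log2 5.09 in beta cells, 4.88 in wild-type ductal cells and 4.91 in deleted ductal cells. Across probe sets, Pearson's r was 0.974 between the ductal arrays, 0.824 between beta and wild-type ductal cells and 0.843 between beta and deleted ductal cells; probe sets are not independent replicates. No value below has a replicate check. Where 1 of the compared levels lay below its array's floor, a fold is a lower bound taken against the floor and written with "at least", while log2 differences and counts of genes past a fold use levels as measured.

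The targeted gene had 2 single-gene probe sets. The main-transcript probe set of Fbxw7 (10492826) read 4.95 in all 3 arrays, below the level floor. The other Fbxw7 probe set (10499093) read 6.32 in wild-type and 5.71 in deleted ductal cells, a difference of -0.61, and 7.00 in beta cells. The position of these probes relative to the floxed part is not given in the sources used here, so these levels do not check the deletion.

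The comparison of deleted with wild-type ductal cells asks which transcripts differ once Fbw7 is removed. Duct epithelial genes were higher in the deleted cells, with a median difference of log2 1.05 over 23 genes, and 12 of them were at least 2-fold higher while 0 were 2-fold lower. Cdh1, the epithelial cadherin, was 6.20-fold higher and Ambp, a secreted protease inhibitor precursor, 7.70-fold higher; Sox9, a duct transcription factor, was 1.84-fold and Krt19, a duct keratin, 1.32-fold higher. Acinar genes were higher too, with a median of 1.67 over 24 genes and 20 of them at least 2-fold higher, among them the trypsin inhibitor Spink1 (6.85-fold), the phospholipase Pla2g1b (5.12-fold) and the carboxypeptidase Cpa1 (2.56-fold). Mesenchymal genes were lower, with a median of -0.87 over 14 genes and 7 of them at least 2-fold lower, including the growth factor receptor Pdgfra (3.96-fold) and the collagen Col1a2 (2.51-fold). The ductal and acinar medians lay above 100% and the mesenchymal median above 0% of their random lists.

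Some members of these lists went the other way, did not differ or differed little. The water channel Aqp1 was at -0.51 and the bicarbonate transporter Slc4a4 was identical in both arrays. The protease Ctrc was 2.31-fold lower, and its difference was -0.96 after quantile normalization. Among mesenchymal genes, Rgs5 was at 0.66 (0.07 against the floor) and the proteoglycan Dcn at -0.22. Genes of mesenchymal transition had a median of -0.41 over 12 genes, above 0.040% of random lists, with Fn1, the matrix protein fibronectin, at -1.32 and Cdh2, the neural cadherin, at -1.31. Mesothelial markers, a list added after the largest differences had been seen, had a median of -0.01 over 16 genes, 8 of them higher and 8 lower.

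Counted over single genes, 144 of 10035 were at least 2-fold higher and 182 at least 2-fold lower in the deleted cells, so that 44.2% of the 326 were higher; 82 of the 326 had 1 level below the floor, and 285 stayed at least 2-fold apart with such levels raised to the floor. After quantile normalization 140 were higher and 93 lower (60.1% higher), and 230 of these genes were among the 326. The antimicrobial lectin Reg3b was 24.4-fold higher, and other genes among the most positive differences were the epithelial immunoglobulin transporter Pigr (at least 6.75-fold), Tm4sf4 (9.05-fold), the homeobox factor Prox1 (at least 7.19-fold), the nucleoside transporter Slc28a3 (8.32-fold), the epithelial ETS factor Ehf (7.97-fold), the carboxylesterase Ces1d (6.77-fold) and Gprc5c (6.50-fold). The chitinase-like genes Chil4 and Chil3 had the most negative measured differences, -6.08 and -4.66; both read below the floor in deleted cells, and against the floor the differences were -3.45 and -3.67. They are close paralogs whose probes can share signal. Tdo2, a tryptophan dioxygenase, was at least 4.81-fold lower, the carbonic anhydrase Car4 7.65-fold, the interferon-induced GTPase Gbp2b at least 4.74-fold lower, and the guidance factor Sema3a was at -2.69 (-2.14 against the floor). Bst1 (5.07-fold) and the actin-binding Cotl1 (4.69-fold) were lower as well. Of 24 genes at least 2-fold apart that had a further probe set above the floor, 22 had the same sign on it and 9 were also 2-fold apart.

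**Figure D1:**
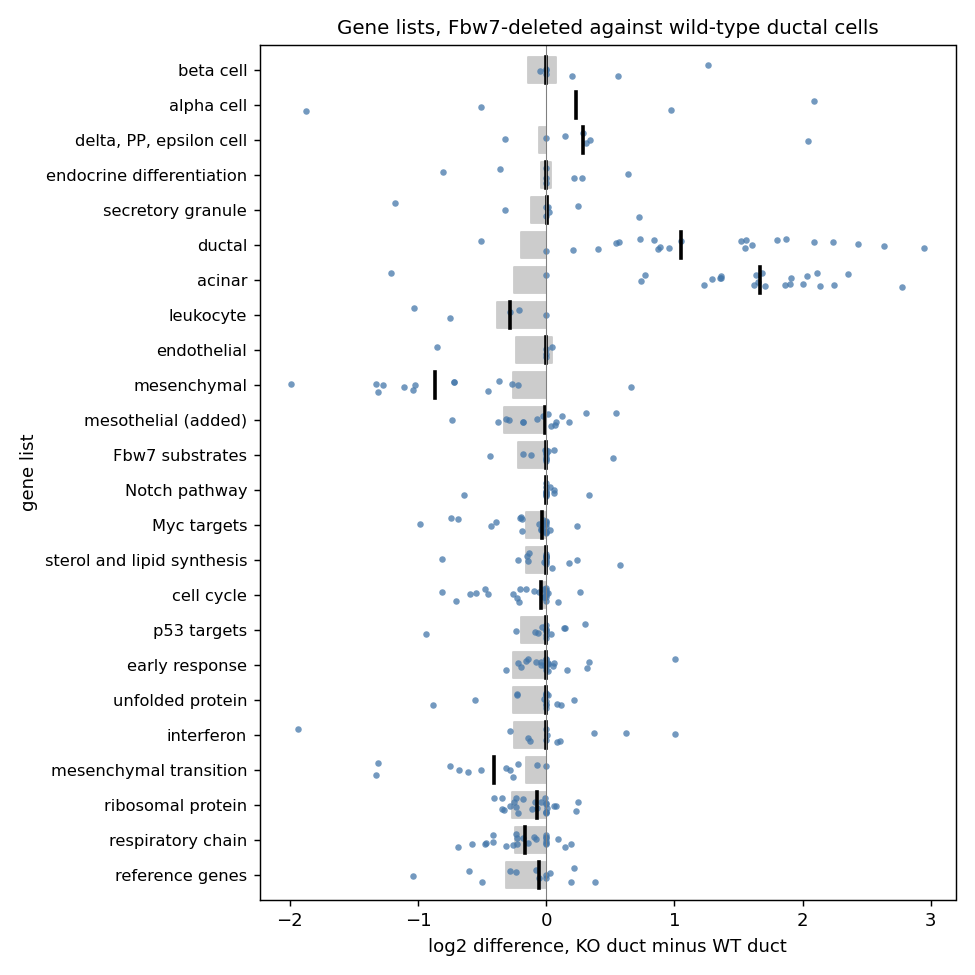
Log2 difference between deleted and wild-type ductal cells (x axis) for genes above the level floor, by gene list (y axis). Each point is 1 gene, the black bar is the list's median and the grey band holds 95% of matched random lists, drawn for lists of at least 5 genes. The ductal and acinar medians, 1.05 and 1.67, lie to the right of their bands and the mesenchymal median, -0.87, to the left.

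Transcripts of 5 islet hormones read slightly higher in deleted than in wild-type ductal cells and stayed far below beta cell levels, while Ghrl, the ghrelin gene, read 5.82 in both ductal arrays. Ins2, an insulin gene, read 5.87 against 5.31, the glucagon gene Gcg 5.75 against 4.77, the somatostatin gene Sst 5.40 against 5.06 and the pancreatic polypeptide gene Ppy 6.00 against 5.71; Pyy, the peptide YY gene, named here because it leads the beta cell comparison, read 6.00 against 5.68. Gcg and Sst were below the floor in wild-type cells, and against it their differences were 0.51 and 0.17. Beta cell markers had a median of 0 over 7 genes (51.7% of random lists), with 1 gene at least 2-fold higher, the glucose transporter Slc2a2 (2.40-fold). Markers of delta, PP and epsilon cells had a median of 0.28 over 7 genes, above 99.9% of random lists and 0.17 with levels raised to the floor, led by Hhex (at least 4.02-fold), a homeobox factor; without genes identical in both arrays the percentile was 96.8. The 4 alpha cell markers above the floor went both ways, from the transthyretin gene Ttr at 2.09 to Slc7a2 at -1.87 (-1.77 against the floor). Unlike the hormones, Hhex, Slc2a2 and Ttr read higher in deleted ductal cells than in beta cells (7.24 against 6.05, 6.90 against 6.05 and 9.44 against 9.25). Neurog3, the endocrine progenitor factor, read 4.20 in both ductal arrays, below the floor. Endocrine differentiation genes had a median of 0 over 8 genes and secretory granule genes 0.0059 over 8 genes (97.2%), both within their random lists; with all measured members the secretory granule list lay above 99.98% and the beta cell list above 99.97%.

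Lists tied to known Fbw7 functions had medians near 0, in part because many members were identical in both arrays. Genes encoding Fbw7 substrates had a median of 0 over 14 genes, 7 of them identical and 0 of them 2-fold apart, from Nfe2l1 at -0.44 to Klf5 at 0.52. Fbw7 acts on protein stability, which these arrays do not measure. Myc was at -0.01 and Jun at 0.02, and Ccne1, the cyclin E1 gene, read below the floor in both arrays. Notch pathway genes had a median of 0 over 13 genes, 8 of them identical in both arrays, among these the Notch target Hes1. Myc targets had a median of -0.04 over 24 genes, 15 of them lower and 2 higher, from Rrs1 at -0.98 to Fbl at 0.24. Sterol and lipid synthesis genes had a median of 0 over 20 genes, 10 of them identical, from Elovl6 at -0.81 to Scd2 at 0.58. The median was also 0 for p53 targets (15 genes) and unfolded protein response genes (17 genes). It was 0 too for 24 early response genes, a list of genes that respond to tissue dissociation, with Ccn1 2.01-fold higher. All of these lists lay within their random lists.

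Of 22 lists with at least 5 genes above the floor, 4 lay above, 3 below and 15 within their random lists. Cell cycle genes were below with a median of -0.04 over 26 genes (1.38%), 0 of them 2-fold apart; Cdk1, a mitotic kinase, was at -0.81. Without genes identical in both arrays the cell cycle list was at 21.1%, and with each array centred its median was 0.00042. Interferon genes were above with a median of 0.0026 over 12 genes (99.5%), with Ifit3 higher and Oas1a, an antiviral enzyme, at -1.94 (-0.82 against the floor); the list was within its random lists after quantile normalization (93.1%). Ribosomal protein genes had a median of -0.07 over 25 genes, respiratory chain genes -0.16 over 24 and reference genes -0.06 over 13. Leukocyte genes had a median of -0.29 over 5 genes (5.53%), with the class II gene H2-Ab1 at -1.03 (-0.80 after quantile normalization), endothelial genes a median of 0 over 5, and the 1 red cell gene above the floor, Slc4a1, was at 0.24 (0.09 against the floor).

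**Figure D2:**
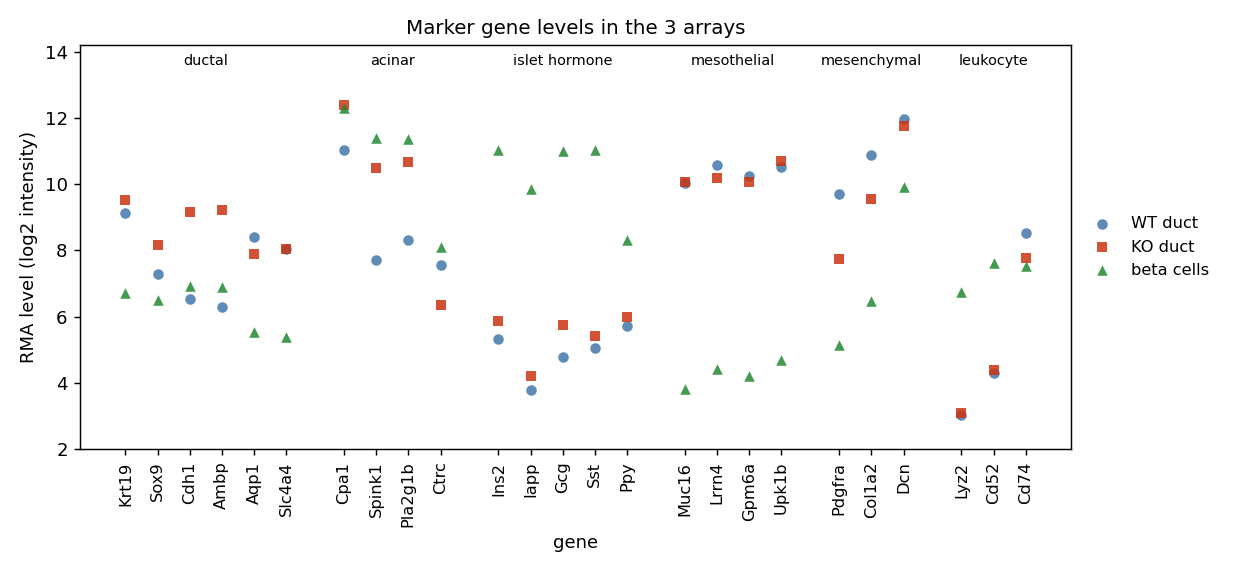
RMA level in log2 intensity (y axis) of marker genes (x axis) in the 3 arrays, with 1 point per gene and array. Mesothelial genes such as Muc16 read 10.05 and 10.07 in the ductal arrays and 3.82 in beta cells, while Ins2 read 11.04 in beta cells and under 6 in both ductal arrays.

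The comparison of beta cells with wild-type ductal cells sets 1 sorted array against another, and neither held signal of 1 cell type only. In the wild-type ductal array some duct markers, named here for their level, read low: Prom1 (4.91) and Cftr (4.95) below the floor and Epcam (5.42) near it. Others read high there, such as Krt8 (9.38) and Krt19 (9.13), as did the acinar gene Cpa1 (11.03). Of 19 measured beta cell markers, 13 were above the floor. They had a median of 1.14, with 7 of them at least 2-fold higher in beta cells, led by Iapp, the islet amyloid gene (at least 24.6-fold), and Ins2 at 5.73. With levels below the floor raised to it, the median was 0.69. Gng12 went the other way, at -2.26, and Mafa was identical in both arrays. Pdx1 (5.14) and G6pc2 (4.83), named here for their level, read below the floor even in the beta cell array. Secretory granule genes had a median of 1.37 over 16 genes, with 10 at least 2-fold higher, such as the granins Scg3 (at least 3.88-fold) and Chga (at least 4.14-fold), and a median of 0.84 with levels raised to the floor, while Cpe and Pam, a prohormone carboxypeptidase and an amidating enzyme, were at -2.24 and -2.36. Hormones of other islet cells were also higher: Gcg at least 54.5-fold, Sst at least 55.8-fold, Pyy 20.1-fold and Ppy 6.09-fold. The delta, PP and epsilon list had a median of 0.85 over 7 genes and the alpha cell list 0.51 over 7; the alpha cell list lay above 98.8% of random lists as deposited and above 92.1% after quantile normalization.

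Markers of acinar cells, leukocytes and endothelium were higher in the beta cell array than in wild-type ductal cells, while mesenchymal markers had a median of -1.77 over 14 genes (2.91% of random lists), 13 of them lower, and the mesothelial markers added later a median of -4.71 over 16 genes, all lower. Acinar genes had a median of 2.17 over 24 genes and 21 of them were at least 2-fold higher, led by Spink1 (12.8-fold) and Gp2 (11.4-fold), and Cuzd1, a zymogen granule gene, was 16.1-fold higher. Leukocyte genes had a median of 1.91 over 13 genes, with Lyz2, a lysozyme of myeloid cells, at least 2.82-fold and Cd52 at least 5.22-fold higher and the class II chain gene Cd74, the 1 lower member, at 7.53 against 8.53; with levels raised to the floor the median was 0.64. Endothelial genes had a median of 0.86 over 12 genes, with Emcn at least 3.44-fold and Pecam1 at least 2.83-fold higher, and a median of 0.66 with levels raised to the floor; Cd34 and Esam went the other way, at -3.49 and -0.61. Trdn, the muscle protein triadin, was 46.6-fold higher on the probe set used, but its 19 probe sets ranged from 0.08 to 6.76.

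Genes lower in beta cells included many that read high in both ductal arrays. The acute-phase gene Saa3 was at least 89.7-fold lower, the protease inhibitor Timp1 at least 59.9-fold, Serpinb2 at least 54.6-fold and the mucin Muc16 at least 26.9-fold lower. Krt19 was at -2.42 and Sox9 at -0.78, yet the ductal list had a median of -0.05 over 23 genes (84.3% of random lists), 8 of them at least 2-fold lower. Sterol and lipid synthesis genes had a median of -1.36 over 20 genes, with Idi1 at least 2.67-fold and Scd2 at least 9.48-fold lower. Cell cycle genes had a median of -1.01 over 26 genes, with the nucleotide reductase Rrm1 at least 8.67-fold lower, and Myc targets -1.29, p53 targets -1.31 and interferon genes -1.37. These 5 lists were below their random lists and 7 were above, out of 23. Medians of similar size or lower were also found for reference genes (-1.72), respiratory chain genes (-1.58) and ribosomal protein genes (-1.32). Those lists lay within their random lists, so falls of this size were not particular to the lists called below. With the floor at the 75th percentile, the median over all genes was -0.69.

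In all, 710 of 11139 genes were at least 2-fold higher and 2875 at least 2-fold lower in beta cells, so 19.8% of the 3585 were higher. Of the 3585, 1271 had 1 level below the floor, and with such levels raised to it 327 were higher and 2704 lower. This split moved with the scaling: 37.2% were higher after quantile normalization, 39.2% with each array centred, 33.6% with the loess trend and 33.9% without a floor. The median over all genes was -0.11 as deposited, and quantile normalization, centring and the loess trend moved it up by 0.21, 0.34 and 0.13, so differences of single genes between beta and ductal cells hold relative to such a shift.

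**Figure D3:**
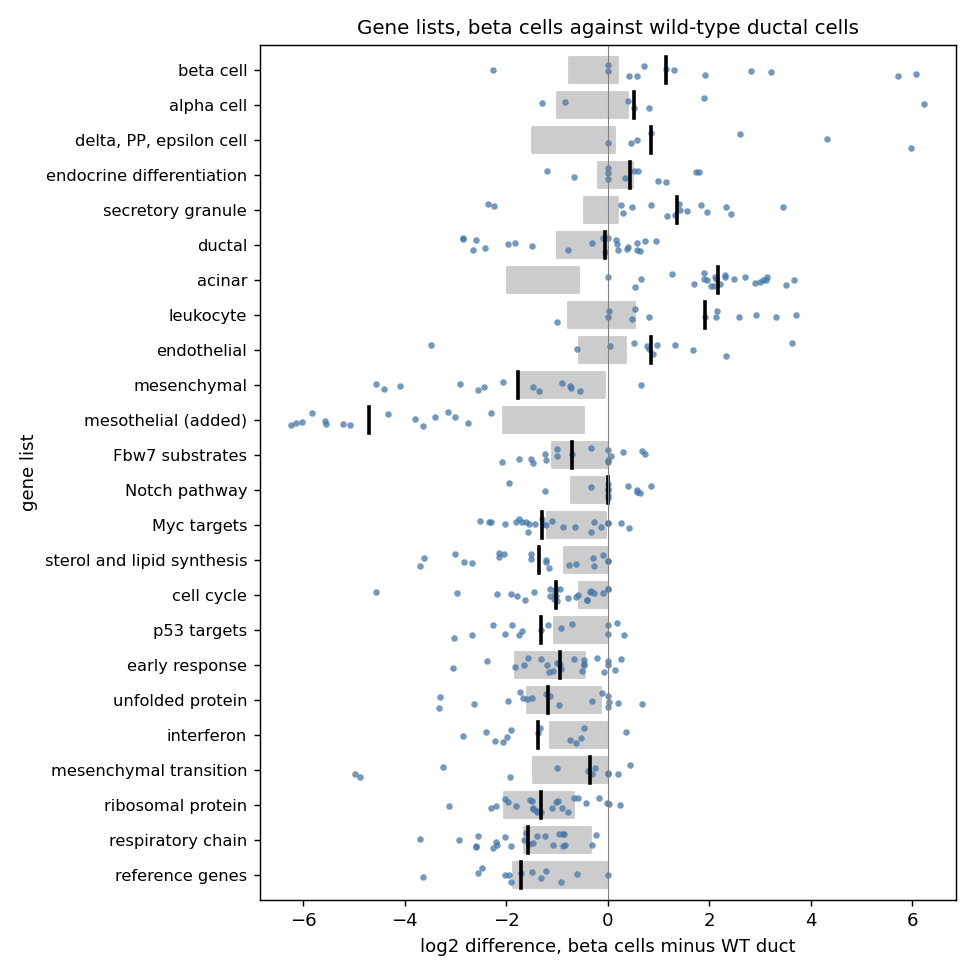
Log2 difference between beta cells and wild-type ductal cells (x axis) for genes above the level floor, by gene list (y axis). Points are genes, black bars medians and grey bands 95% of matched random lists. The acinar and leukocyte medians, 2.17 and 1.91, lie to the right of their bands, and the mesothelial median, -4.71, lies to the left.

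Against deleted ductal cells, the beta cell array had the same leading hormones: Sst was 49.6-fold, Gcg 38.3-fold, Ins2 36.0-fold and Iapp at least 24.5-fold higher. Ductal genes were lower in beta cells, with a median of -1.90 over 24 genes and 20 of them at least 2-fold lower, among them Tspan8 at -3.68 (-3.32 against the floor) and the keratin Krt18 (7.34-fold). Acinar genes were higher in beta cells by a median of 0.69 over 24 genes, with 6 at least 2-fold higher. The count was 569 genes at least 2-fold higher and 2552 lower of 11095, or 18.2% higher (258 and 2358 with levels raised to the floor), against 35.7% after quantile normalization, 37.7% with centring, 29.7% with the loess trend and 32.0% without a floor. Of 23 lists, 7 lay above, 6 below and 10 within their random lists.

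Whether deleted ductal cells lay nearer to the beta cell array was measured on 102 genes. Their measured level was at least 4-fold higher in that array than in wild-type ductal cells. They are not a list of beta cell markers, because acinar, leukocyte and endothelial markers were higher in that array too. Of the 102 genes, 80 (78.4%) were higher in deleted than in wild-type ductal cells, 14 lower and 8 identical. Their median difference was 0.41, with 29 genes at least 2-fold higher. Simulated unchanged ductal arrays gave 57.8% on average (45.4% to 71.4% over 100 simulations), because both differences use the wild-type array. With the genes chosen against the deleted ductal array instead, which turns that bias around, 36 of 63 (57.1%) were higher. Their median was 0.07, and 4 of them were at least 2-fold higher. This choice was not simulated, so 57.8% is not a reference value for it. Over 11291 genes, of which 18.5% were higher in deleted cells, Pearson's r between the differences was 0.44 against 0.12 in simulation and the covariance 0.19 against 0.042. The correlation is across genes, which are not independent replicates, and with 1 array per group part of the excess may come from the shared array. Acinar genes, which were higher in both arrays, were among the 102. Without that list 64 of 86 (74.4%) were higher, but the median fell to 0.30 and the genes at least 2-fold higher from 29 to 13. Cuzd1, a zymogen granule gene that is not on that list, stayed in, at 6.09 in wild-type and 8.08 in deleted ductal cells.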

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

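All tests of explanations in this part were chosen after the result they address had been seen.

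Among probe sets with no gene listed, which no comparison used, 348 of 4034 above the floor were at least 2-fold higher in deleted than in wild-type ductal cells and 345 were at least 2-fold lower. Differences reached 4.51 and -4.88. The share higher was 8.63%, against 1.44% of named genes, and the share lower 8.55%, against 1.81%. The differences spread more widely (SD 0.86 against 0.39) and nearly evenly to both sides, which wider noise would give too; what these probe sets target was not analysed here.

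Ductal and acinar genes were higher and mesenchymal genes lower in the deleted ductal array. Whether acinar RNA carried into the sort was the source of the ductal genes could not be decided. The 12 ductal genes at least 2-fold higher had a median of -1.87 in the beta cell array relative to the deleted array. All 12 of 12 lay lower there, although acinar genes were higher there by 0.69. Reference genes also lay lower there, with a median of -1.51 over 12 genes and 11 of them lower. Lower readings in that array therefore do not decide the question. A smaller share of all non-epithelial cells could not be decided either. Mesothelial and mesenchymal medians differed by 0.86, with interquartile ranges of -0.21 to 0.09 and -1.23 to -0.39, so these lists did not fall together. Mesothelium is known to express Krt19, whose promoter drives the Cre used for labelling. Its genes therefore need not fall with those of unlabelled cells. A larger share of duct epithelial and acinar cells, or of their RNA, cannot be told apart from a change within the cells: 43 of 47 ductal and acinar genes (91.5%) were higher, which either would give, and 1 array per group keeps it open. An effect of Fbw7 deletion stays open as an untested biological explanation.

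Leukocyte, endothelial, acinar and other islet hormone genes were higher in the beta cell array than in wild-type ductal cells, although cells were sorted for a fluorescent reporter of the insulin promoter. The narrower spread of the beta cell array is argued against as the whole cause for the leukocyte list, which lay above 100% of random lists matched on the wild-type ductal level; its median was 0.64 with levels below the floor raised to it. Other cell types or their RNA in the beta cell sort would give medians that stay above 0 after quantile normalization. Those of the leukocyte, endothelial and acinar lists did, the smallest of these being 0.92, for endothelial genes. The alpha cell median was 0.49 in that setting and that of delta, PP and epsilon cells 1.04. The alpha cell list lay above only 73.8% of random lists matched on the wild-type ductal level, so spread stays open for it. A difference in the beta cells themselves was not tested.

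Chil4 and Chil3 led 15 genes whose measured level was at least 4-fold lower in deleted ductal cells; 11 stayed so with levels below the floor raised to it. A smaller share of mesenchymal cells could not be decided for Chil4 and Chil3. The nearer of them to 0 lay beyond the most negative mesenchymal marker by -2.67 as measured (Chil3) and by -1.47 with levels raised to the floor (Chil4). Both genes were picked for their most negative differences, so this margin follows in part from the choice. Macrophages in the wild-type sort are argued against by 5 of 7 macrophage genes, which such cells would bring along. These 5 read below the floor there, although 4 of them read above it in beta cells, so their probes could have shown such cells. The other 2, Csf1r (5.83) and Cd68 (5.89), read above the floor there and were at 0 and -0.21 in deleted against wild-type ductal cells. The class II genes Cd74 (8.53), H2-Ab1 (7.67) and H2-Aa (7.57) read high there and were at -0.75, -1.03 and -0.29. Other leukocyte signal in the wild-type sort therefore stays open. The 7 macrophage genes were higher in beta cells than in wild-type ductal cells by a median of 1.91 (0.64 with levels raised to the floor), where Chil4 and Chil3 were at -5.84 and -4.26 (-3.39 and -3.60). A strain haplotype carried along with the floxed allele cannot be told apart from other causes. Of the 200 tested genes nearest to Fbxw7 in assembly GRCm38.p6, 10 were at least 2-fold apart, against a median of 6 and an upper bound of 15 in other runs of 200, and 4 of the 15 genes (Chil3, Chil4, Gbp2b and Tdo2) lie on its chromosome, which holds 4.79% of tested genes. An effect of Fbw7 deletion on these genes was not tested.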

How the results depend on the processing

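Leaving out marker lists or genes identical in both ductal arrays, and raising levels below the floor to it, was chosen after seeing the data. Counts of genes apart stayed within 1.5 times of the reported count under every alternative except the fold threshold. At 1.5-fold there were 1010 genes for deleted against wild-type ductal cells, 5583 for beta cells against wild-type and 5154 for beta cells against deleted ductal cells; at 4-fold there were 56, 1253 and 978, as the thresholds themselves bring about. Of the 56, 41 were higher. Lists outside their random lists numbered 7, 12 and 13 in these comparisons; for beta cells against wild-type ductal cells the number was 19 without matching on level, a cause not tested, and in the other settings the numbers were 5 to 9, 12 to 13 and 12 to 19. Ductal, acinar, mesenchymal and mesenchymal transition lists kept their side in deleted against wild-type ductal cells under every setting, and of the lists outside their random lists only cell cycle changed sign, to 0.00042 with each array centred. Lists within them changed sign too, such as Myc targets (0.03) and reference genes (0.01) after quantile normalization, and early response genes in beta against wild-type ductal cells, from -0.94 to 0.44 with the loess trend. The cause was not tested. Without identical genes the delta, cell cycle and interferon lists lay within their random lists. In the ductal comparison, lists reported as within lay above in other settings: beta cell markers with all measured members (99.97%) and after quantile normalization (97.9%), secretory granule genes with all members (99.98%) and with levels raised to the floor (97.6%), Fbw7 substrates and Notch genes with the loess trend (both 97.8%), and early response genes after quantile normalization (99.2%), with the loess trend (99.7%) and without identical genes (98.5%). Ribosomal protein (1.53%) and respiratory chain genes (0.22%) lay below without matching. With levels raised to the floor, Myc targets in beta against deleted ductal cells lay within (6.75%). Among genes chosen as higher in the beta cell array, the share higher in deleted ductal cells was 57.1% when they were chosen against the deleted array. It was 64.2% at a 2-fold definition (simulated unchanged cells 54.4% to 62.2%). After the loess trend, which leaves no ties, it was 86.3% (simulated 46.4% to 65.8%), and 51.9% of all genes were higher. With levels raised to the floor it was 71.2% (42 of 59), against 14.6% of all genes and a simulated 30.4% to 56.1%; simulated arrays hold fewer ties than the measured ones. It was 79.5% without a floor and 74.4% without acinar genes or without 5 marker lists. The Fbxw7 difference ranged from -0.31 to -0.61. No paired analysis was possible because each group is 1 array. Signal near the floor limits transcripts such as Neurog3, whose difference was not detectable at this level.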

Other observations

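The mesothelial list in this part was chosen after the largest differences had been seen, and no test of an explanation is reported here.

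Both ductal arrays read far above the beta cell array for genes known from mesothelium, the cell layer that covers abdominal organs. Muc16 read 10.05 in wild-type and 10.07 in deleted ductal cells against 3.82 in beta cells, Upk1b 10.52 and 10.70 against 4.69, Lrrn4 10.57 and 10.20 against 4.42, and Gpm6a 10.24 and 10.06 against 4.21. All 16 mesothelial genes above the floor were at least 2-fold lower in beta cells than in wild-type ductal cells, with a median of -4.71. Krt19, whose promoter drives the Cre used to label ductal cells, is known to be expressed in mesothelium too.

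Other genes with the most negative differences between beta and wild-type ductal cells were not all alike in the ductal arrays. Saa3 read 11.79 in wild-type and 11.36 in deleted ductal cells against 3.63 in beta cells, and Chil1 10.82 and 11.30 against 4.97. Serpinb2 read 11.07 and 9.38 against 4.57, Timp1 11.21 and 10.17 against 4.77, and Serpina3n 10.59 and 9.84 against 4.77.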
